A study of Mus musculus with 2 samples.

How the data were processed

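In situ Hi-C with the restriction enzyme DpnII was performed on primary immediate neuronal precursors sorted by fluorescence from the olfactory epithelium of FVB/NTac pups of mixed sex, per the labels. The labels give 2 biological replicates, of 2200000 and 2100000 cells, fixed in 1% formaldehyde. They form a single group, so no comparison between conditions was possible. The comparisons made were between boundaries and shifted positions, between boundary classes and between chromosomes.

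The contact lists of both replicates were combined into a contact matrix on GRCm38, and boundaries were called on that matrix, per the series' design text and the submitters' processing notes for the build. The caller, its window and its cutoffs are not given in the sources used here. The deposited list analysed here gives for each 5 kb interval a class and a score, and the score is the authors' own value per boundary, used here only to describe, rank or filter boundaries within this list. From the values, the strong class begins at a score of 0.5 and the weak class at 0.2. Because replicates were pooled before calling, the spread between replicates, the contact number of each replicate and the effect of depth on the calls are unknown here. Contact matrices, contact lists, insulation tracks and compartment tracks were not analysed here. Pooling gives more contacts per bin but lets a deeper replicate weigh more, and calls on a combined matrix can hold boundaries present in 1 replicate alone.

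Sequence came from GRCm38.p6 and genes from GENCODE M21, the same build as the list, and 0 intervals lay outside the reference chromosomes. The tRNA genes came from the RefSeq table of the same assembly. The TSS was the 5′ end of the gene model, so alternative promoters were not considered. Bins of 5 kb with at least 50% assembled sequence on the 19 autosomes and chromosome X were used, and no boundary was listed on chromosome Y. The strain of the cells differs from that of the reference, and strain variants were not examined.

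A boundary counted as near a TSS or motif when the boundary interval extended by 10 kb on each side, in whole 5 kb bins, held it. For lists of genes, the share of members near a boundary was tested in the same way. The observed value was set against 10000 circular shifts of the boundaries along the bins of each chromosome, by at least 1 Mb, which keep their spacing. Shifts and rotations are restricted permutations, and their p is called a permutation p. These tests were two-sided, as were all others, and the ratio is observed over expected. Its standard error is a jackknife over chromosomes. Adjusted p values are Benjamini-Hochberg over the 17 gene lists, the 3 measures of strong against weak boundaries or the 3 places in genes. Strong and weak boundaries, and boundaries inside and outside receptor clusters, were compared by 10000 rotations of the labels along each chromosome. For boundaries inside clusters against others of like composition, the class was instead permuted 10000 times within strata of composition, across all chromosomes. This takes boundaries as independent, and its p is also called a permutation p. Matched lists were 10000 random draws. Olfactory receptor clusters were runs of at least 5 receptor genes with gaps of at most 500 kb. Chromosome X was ranked among the 20 chromosomes with an exact p. CTCF sites were exact matches to CCASYAGRKGGC on either strand, and their orientation was tested with 100000 permutations of strands within boundaries. Shares carry Wilson 95% intervals, which cover counting error only and treat boundaries as independent. The interval of the median spacing came from 1000 bootstrap resamples of chromosomes.

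Apart from the places in genes and the permutations within strata of composition, the tests above were fixed before the data were examined. So were the 17 lists and the rule for named genes. The strata were chosen after the lower strong share inside receptor clusters had been seen. The rule named the 10 boundaries with the highest score with up to 2 genes starting within 20 kb, up to 4 members of each list within 10 kb of a boundary by that boundary's score, all precursor regulators, and the 5 receptor clusters with the most genes. Some genes that the rule names are not reported here. Drg1, which hosts the strongest boundary, was named after its values were seen. The places in genes, the boundaries flanking receptor clusters, the score quartiles, the sequence features inside clusters and the share of repeated sequence were examined after the list had been seen. Repeated sequence was measured as the share of sampled 50-mers (1 in 32) that occur once in the reference, and a bin counted as mostly repeated below 50%. Markers of other cell types were included because a sort can retain such cells, and expression was not analysed here.

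Alternatives fixed beforehand were strong boundaries alone, boundaries at or above the median score, boundaries within 50 kb merged, chromosome X left out, independent random placement, extensions of 0, 25 and 50 kb, all annotated genes, random lists matched on the number of protein-coding starts within 100 kb, cluster gaps of 200 kb and 1 Mb, a second CTCF consensus, matches outside repeats, flanks of 25 and 100 kb, plain permutation, and upper against lower scores. Mostly unique bins, and lists matched on GC content as well, were added after seeing the data. For the latter, genes were drawn with replacement within strata, because drawing without replacement left some olfactory receptor genes unmatched; keratin genes passed the threshold with the first way of drawing and not with the second.

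The tests were tested on simulated data built on the same 7841 boundaries. Of 100 shifted lists with nothing planted, 4% gave p under 0.05, as did 5% of 100 rotations of random values. Shares near 5% follow from how these null data were made. They check the code and not whether the shifts and rotations suit the real data. When 2, 5 and 10% of boundaries were moved to gene starts, 18.7, 21.2 and 25.1% were found near one, against 18.8, 21.3 and 25.4% planted. These were called in 95, 100 and 100% of 20 runs each. A planted strand difference of 40 points was found as 40.6 points. The work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, bedtools 2.31.1 and matplotlib 3.10.9.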

Results

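Immediate neuronal precursors are the cells of the olfactory epithelium that are about to leave the cell cycle and become olfactory sensory neurons. They were sorted from mouse pups of mixed sex that carried a GFP reporter of Ngn1 (Neurog1), and their chromosome folding was measured by in situ Hi-C, which ligates DNA ends that lie close together in fixed nuclei. There were 2 biological replicates of a single group, of 2200000 and 2100000 cells. The list analysed holds 7841 domain boundaries, which are positions where contacts between the sequence on either side are depleted. Each has a class and a score from the authors, and a higher score marks stronger insulation. The boundaries were called on the contact matrix combined from both replicates, so no value has a replicate error, and the sequencing depth behind the calls is unknown. Errors below are intervals or standard errors over boundaries or chromosomes.

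Boundaries were spread along all 19 autosomes and chromosome X. The median distance between neighbours was 265 kb (95% bootstrap interval over chromosomes 260 to 275 kb), with quartiles of 185 and 390 kb. Of the 7841 boundaries, 4137 were strong and 3704 weak, a strong share of 52.8% (Wilson 95% interval 51.7 to 53.9%). Strong boundaries had a median score of 0.874 and weak ones 0.301, and the highest score was 3.78.

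The strongest boundary of the list lay on chromosome 11 (GRCm38, 3195001 to 3200000, score 3.78), inside an intron of Drg1. The start of Sfi1, a centrosome gene, was 1.54 kb from it and that of Eif4enif1, which encodes a carrier of a translation factor, was 2.39 kb from it. The next strongest (chromosome 13, 56180001 to 56185000, score 3.57) was intergenic, 1.12 kb from the start of Tifab, and was also the boundary nearest to Neurog1. The mice carried a GFP reporter of this gene, and whether the reporter affects contacts measured around it was not examined. Intergenic here means outside protein-coding genes, and genes of other classes were not considered. The seventh (chromosome 2, 37350001 to 37355000, score 2.90) overlapped an exon with untranslated sequence of Pdcl, whose start was 4.33 kb away. The ninth (chromosome 1, 88290001 to 88295000, score 2.69) lay in an intron of the cold receptor gene Trpm8, 12.3 kb from its start and 12.4 kb from that of the centromere gene Hjurp. The fourth (chromosome 12, 64900001 to 64905000, score 3.25) was intergenic, 12.9 kb from Gm527. The other 5 of the 10 strongest were intergenic and had no protein-coding gene start within 20 kb. They lay on chromosome 5 from 15685001 (score 3.33), chromosome 12 from 115830001 (2.996), chromosome 7 from 37360001 (2.90), chromosome 17 from 52555001 (2.71) and chromosome 8 from 95940001 (2.68). Around the boundaries on chromosome 5 and at 115830001 on chromosome 12, 65.9% and 39.0% of the bins within 100 kb held mostly repeated sequence. For the 78 strongest boundaries the mean share of such bins was 5.94%, against 4.02% for the other 7763. At least 25% of such bins surrounded 3.85% of the 78, against 0.374% of the others. Whether repeated sequence raised these scores was not tested.

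Chromosome X had the fewest boundaries per Mb of assembled sequence and the lowest strong share of the 20 chromosomes. It had 2.64 boundaries per Mb, against an autosome median of 3.06 (range 2.72 to 3.76 over 19 autosomes). Repeated sequence is counted in this density. Chromosome X held stretches without a boundary of 11.6, 3.48 and 2.84 Mb, in which 11.9, 17.7 and 21.4% of the sequence was unique. Some autosomes held such stretches too. Density in mostly unique sequence was not compared between chromosomes, so whether repeated sequence accounts for the lowest rank in density was not tested. The strong share on chromosome X was 32.9% (Wilson 95% interval 28.7 to 37.5%), against an autosome median of 54.7% and a lowest autosome, chromosome 12, of 47.4%. Its median score was 0.363, against 0.564 for the median autosome, and neighbouring boundaries were 300 kb apart, against 265 kb. Strong boundaries numbered 0.869 per Mb, against 1.66. Among autosomes, chromosome 11 had the highest density and chromosome 19 the highest strong share, 63.1%. Ranked among 20 chromosomes, a single one cannot give a two-sided exact p below 0.1, and chromosome X had that value for density, strong share, score and spacing. Autosomal boundaries with the GC content, gene starts and motif matches of those on chromosome X were strong in 40.4% of cases.

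**Figure D1:**
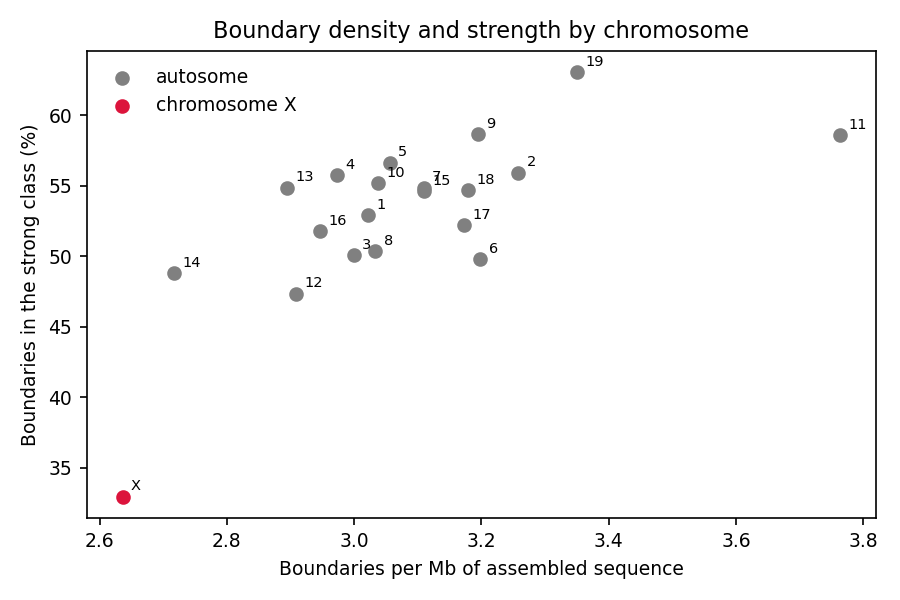
Boundaries per Mb of assembled sequence (x axis) against the percentage of boundaries in the strong class (y axis), one point per chromosome, with autosomes in grey and chromosome X in red. Chromosome X lies lowest on both axes, at 2.64 per Mb and 32.9%.

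Boundaries of the precursors lay near gene starts more often than shifted positions did, though most had none nearby. Of the 7841 boundaries, 2687 had the transcription start site (TSS) of a protein-coding gene within 10 kb, 34.3% (Wilson 95% interval 33.2 to 35.3%). Boundaries shifted along their chromosomes had one in 17.1% of cases. The ratio was 2.01 ± 0.064 (jackknife standard error over 20 chromosomes), with a permutation p = 1e-04, the smallest that 10000 shifts can give. Seen from the genes, 3563 of 21724 protein-coding genes (16.4%) started within 10 kb of a boundary, against 7.75% by shifts. Exons of protein-coding genes were overlapped by 2725 boundaries, 34.8% against 22.4% by shifts, and 1921 of these overlapped untranslated regions. Introns held 1074 boundaries, 13.7% against 21.4%, and 4042 lay outside protein-coding genes, 51.6% against 56.2%. Each of these 3 places differed from the shifts with an adjusted permutation p of 1e-04. The places exclude each other, and an interval that overlapped an exon was not counted under introns. The lower intron share is therefore not a result separate from the higher exon share. Counting gene starts inside the boundary interval alone, the ratio was 3.03 (permutation p = 1e-04).

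**Figure D2:**
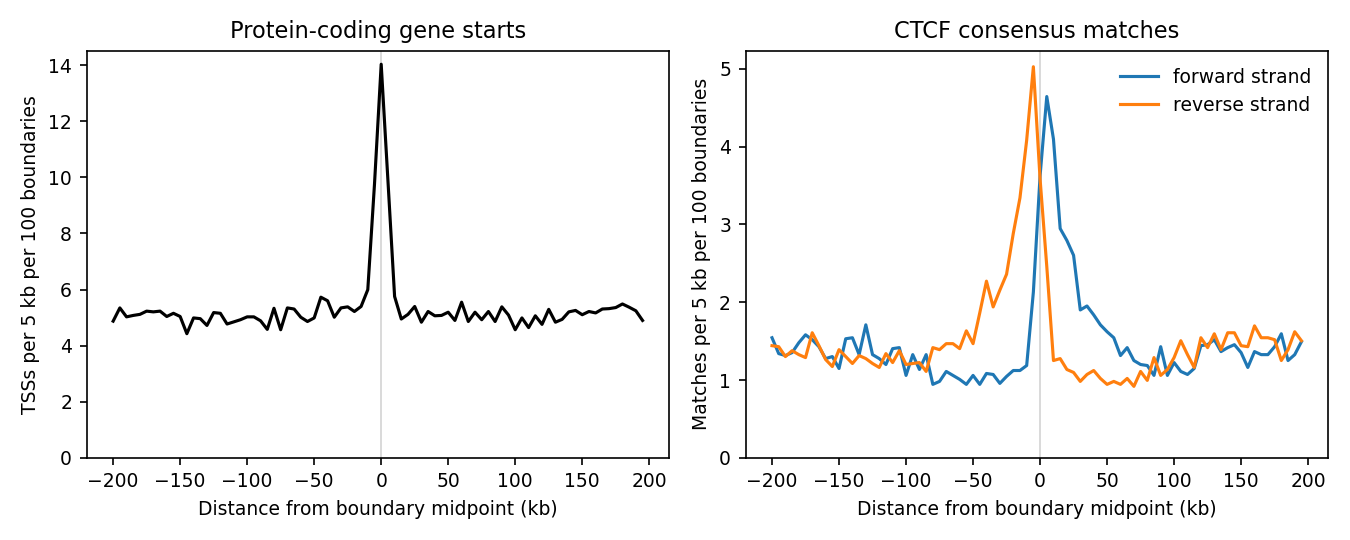
Protein-coding TSSs (left) and matches to the CTCF consensus on the forward and reverse strands (right), per 5 kb and per 100 boundaries (y axes), against the distance from the boundary midpoint in kb (x axes), over 7841 boundaries. Gene starts peak at the boundary, and reverse matches peak on its left side and forward matches on its right.

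Regulators of the precursor state started near boundaries more often than by shifts. Among all protein-coding genes, 16.4% started within 10 kb of a boundary. Of 27 transcription factors, cell cycle genes and other regulators of the neuronal lineage, 11 (40.7%) had a TSS within 10 kb of a boundary, against 7.72% by shifts. The ratio was 5.22 ± 0.97 (jackknife standard error, 12 chromosomes), with an adjusted p of 5.7e-04 over the 17 lists. Lhx2, which encodes a LIM homeodomain factor required for olfactory neurons, started 0.72 kb from a strong boundary (chromosome 2, 38340001 to 38345000, score 0.968). Ebf1 and Ebf3, members of the Olf/Ebf factor family, started 7.32 and 5.56 kb from boundaries with scores of 2.08 and 1.85. Emx2 (3.37 kb, score 1.99), Sox11 (2.57 kb, 1.84), Gadd45g (6.68 kb, 1.19), Sox2 (5.41 kb, 1.10), Cdkn1c (8.95 kb, 0.983) and Insm1 (1.92 kb, 0.818) also lay near strong boundaries. Kit, the stem cell factor receptor gene, started inside a weak boundary interval (score 0.28), and the topoisomerase gene Top2a 0.812 kb from another (score 0.342).

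The proneural gene Neurog1 and the differentiation gene Neurod1 were not among those within 10 kb. The TSS of Neurod1 was 48.3 kb from its nearest boundary (score 0.761) and that of Neurog1 67.2 kb (3.57). Ldb1, the adaptor that binds LIM homeodomain proteins, started 29.8 kb from a boundary with a score of 1.19. Ccnd1, Mcm2, Ebf2, Lgr5, Ebf4, Nhlh1, Mki67, Hes6 and Nhlh2 lay between 19.9 and 64.9 kb away, and Ezh2 295 kb. Against random lists of genes with as many neighbouring gene starts, 18.0% were expected and the ratio was 2.26 (n = 27, adjusted p = 0.0173). With GC content matched as well it was 2.04 (n = 27, adjusted p = 0.0484). Over the bare boundary intervals the call was lost (ratio 2.37, adjusted permutation p = 0.483), and with strong boundaries alone the ratio was 7.89.

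Ribosomal protein genes and genes of the respiratory chain also started near boundaries more often than by shifts. Of 80 cytosolic ribosomal protein genes, 34 (42.5%) started within 10 kb of a boundary, a ratio of 5.48 ± 0.78 (adjusted permutation p = 5.7e-04). The boundaries near Rps24, Rps23, Rpl37 and Rpl38 had scores of 2.32, 2.22, 2.04 and 1.60. Of 93 genes of the respiratory chain and ATP synthase, 35 (37.6%) did so, a ratio of 4.86 ± 0.50 (adjusted permutation p = 5.7e-04), among them Atp5o (score 1.71), Atp5f1 (1.64), Ndufs1 (1.52) and Ndufb10 (1.36). Against lists matched on neighbouring gene starts the ratios were 2.75 (n = 80) and 2.40 (n = 93), both with an adjusted p of 4.2e-04. Widening the boundary intervals from 0 to 50 kb took the ratios from 9.67 to 2.04 and from 11.8 to 1.92.

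Immature neuron markers, nuclear architecture genes and Zfp genes also passed the test against shifts, but not against genes in equally dense surroundings. Markers of immature neurons started near boundaries in 6 of 22 cases (27.3%, ratio 3.63 ± 1.3, adjusted permutation p = 0.0144), among them Stmn2 (score 1.24), Cd24a (1.13), Tex15 (0.646) and Atf5 (0.489). Genes of nuclear architecture did so in 7 of 33 cases (21.2%, ratio 2.76 ± 0.98, adjusted permutation p = 0.0294), including the cohesin subunit gene Smc3 (score 0.849), the cohesin loader gene Nipbl (0.815) and the cohesin regulators Pds5a (0.976) and Pds5b (0.579). Genes named Zfp, most of which encode zinc finger proteins, did so in 48 of 391 cases (12.3%, ratio 1.58 ± 0.26, adjusted permutation p = 0.00467), with Zfp982, Zfp407, Zfp169 and Zfp637 at scores from 1.92 to 2.19. Against lists matched on neighbouring gene starts the ratios of these 3 lists were 1.57 (n = 22, adjusted p = 0.439), 1.27 (n = 33, 0.626) and, turned to below 1, 0.755 (n = 391, 0.0728). With strong boundaries alone the ratios stayed near the main ones, at 3.41, 2.998 and 1.46, but fewer boundaries entered and the adjusted p values were 0.11, 0.0878 and 0.117. The call for immature neuron markers was also lost at 0 kb (ratio 3.03, adjusted permutation p = 0.483) and 25 kb (1.93, 0.131), and that for Zfp genes at 50 kb (1.18, 0.106).

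Markers of other cells of the tissue did not pass the test at 10 kb. Mature neuron markers were near boundaries in 4 of 26 cases (adjusted permutation p = 0.211), which were Ncam2 (score 1.59), Gnal (1.57), Nrp1 (0.847) and Plxna1 (0.575). Horizontal basal cell markers were near them in 2 of 15 cases (Lamb3, 0.743, and Sox9, 0.732, adjusted permutation p = 0.761). Markers of sustentacular, gland and microvillar cells were near them in 2 of 21 cases (Hes1, 0.298, and Aqp5, 0.241, adjusted permutation p = 1). Immune, endothelial, stromal and glial markers were near them in 4 of 20 cases (Cd68, 0.995, C1qb, 0.950, Col1a1, 0.253, and Aif1, 0.238, adjusted permutation p = 0.16). With wider intervals, mature neuron markers passed at 25 kb (ratio 2.30, adjusted permutation p = 0.0178) and 50 kb (2.05, 0.00142), while against lists matched on neighbouring gene starts at 10 kb their ratio was 0.875 (adjusted p = 0.857). The list of immune and endothelial markers passed at 50 kb (1.82, adjusted permutation p = 0.0453).

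Vomeronasal receptor genes, which encode pheromone receptors, were seldom near a boundary. Only 11 of 326 (3.37%) started within 10 kb of one, against 7.77% by shifts, a ratio of 0.434 ± 0.13 (adjusted permutation p = 0.0126). Vmn1r178 lay near the boundary with the highest score (1.29), followed by Vmn2r7 (0.869), Vmn2r99 (0.313) and Vmn2r76 (0.309). Of the 326 starts, 87 lay in bins of mostly repeated sequence, and without such bins the call was lost (ratio 0.703, adjusted permutation p = 0.301). It was also lost over the bare boundary intervals (ratio 0.394, adjusted permutation p = 0.483), and with strong boundaries alone the ratio was 0.147. Against lists matched on neighbouring gene starts it was 0.196 (n = 326, adjusted p = 4.2e-04), and it was 0.328 with GC content matched as well (n = 326, adjusted p = 5.7e-04).

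Olfactory receptor genes, the family from which a mature olfactory neuron expresses a single member, did not differ detectably from shifted positions. Of 1134 receptor genes, 83 (7.32%) started within 10 kb of a boundary, against 7.96% by shifts (ratio 0.919 ± 0.12, adjusted permutation p = 0.696). The highest score near a receptor gene was 2.35, at the edge of the large cluster of chromosome 7 (102485001 to 102490000), next to Olfr544, Olfr543 and Olfr545. Olfr412 on chromosome 11 lay near a boundary with a score of 2.31. Counted against strong boundaries alone the ratio was 0.514 (adjusted permutation p = 0.0129). It was 0.501 against lists matched on neighbouring gene starts (n = 1134, adjusted p = 4.2e-04) and 0.833 with GC content matched as well (adjusted p = 0.2).

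The remaining families did not pass the test. No trace amine receptor gene of 15 started near a boundary (adjusted permutation p = 0.756), and 5 of 56 clustered protocadherin genes did (adjusted p = 0.93), among them Pcdhac1 (score 0.303) and Pcdhgb7, Pcdhga11 and Pcdhga10 at a shared boundary (0.203). Hox genes were near boundaries in 2 of 39 cases, among them Hoxb1 (0.277), with an adjusted p of 0.787. Replication-dependent histone genes were near them in 11 of 67 cases (adjusted permutation p = 0.181), with Hist1h2bl, Hist1h2ai and Hist1h3h at a boundary with a score of 1.41 and Hist1h1a at another (1.38). Of 49 keratin genes only Krt28 was near a boundary (score 0.286, adjusted permutation p = 0.211).

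Inside olfactory receptor clusters boundaries were weaker than elsewhere, while their density did not differ detectably from shifts. The 33 clusters held 1092 of the 1134 receptor genes in 30.4 Mb, with 89 boundaries. That was 2.93 per Mb, against 3.17 ± 0.26 (standard deviation of shifts), a ratio of 0.924 ± 0.085 (permutation p = 0.377). Of the 89 boundaries, 26 were strong (29.2%), against 53.0% of the 7752 outside, a difference of −23.8 percentage points (permutation p = 1e-04, rotated labels). Their median score was 0.347, against 0.536 outside, and their mean score 0.513, against 0.667 (permutation p = 2e-04). Strong boundaries alone were scarcer in clusters than by shifts, with a ratio of 0.485 (permutation p = 1e-04).

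The 5 clusters with the most genes held between 4 and 11 boundaries each. The cluster of 227 genes on chromosome 2 (85330779 to 90403897) held 11 boundaries, 3 of them strong, with a highest score of 1.79. That of 129 genes on chromosome 7 (102476579 to 105369355) held 10, of which 3 were strong. The 95 genes on chromosome 9 (37708964 to 40190134) had 7 boundaries and no strong one, with a highest score of 0.457, and were enclosed by boundaries with scores of 1.65 and 0.889. The 66 genes on chromosome 19 (11826803 to 13921866) had 6 boundaries, 3 of them strong, with a highest score of 1.95. The 60 genes on chromosome 10 (128989431 to 130214403) had 4, of which 1 was strong, with a score of 0.662. The boundaries enclosing the cluster on chromosome 2 were weak, with scores of 0.351 and 0.329. Those on chromosomes 7, 19 and 10 scored 0.995 and 0.770, 0.396 and 1.075, and 2.08 and 0.601. The nearest boundaries on either side of the clusters numbered 66, at up to 1547 kb from the cluster edge, and 41 of them were strong (62.1%, Wilson 95% interval 50.1 to 72.9%), more than inside (Fisher's exact p = 7.2e-05, with boundaries taken as independent). That interval includes the strong share of 53.0% among all boundaries outside clusters. Boundaries inside clusters lay in sequence of 39.2% GC, against 43.1% outside, and 10.1% had a CTCF consensus match within 10 kb, against 26.1%. A protein-coding TSS, the receptors' own included, lay within 10 kb of 71.9% of them, against 33.8%. Against boundaries of like GC content, gene starts and motif matches the strong share inside differed by −10.9 points (permutation p = 0.0166), and against those of like GC content over the surrounding 1 Mb by −10.5 points (permutation p = 0.0385). With gene starts set aside, in a test added after these results, the difference was −7.31 points and did not pass (permutation p = 0.121). All of these stratified tests were chosen after the lower strong share inside clusters had been seen. They took boundaries as independent, whereas rotations keep the order of neighbours, so their p values may be too small.

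**Figure D3:**
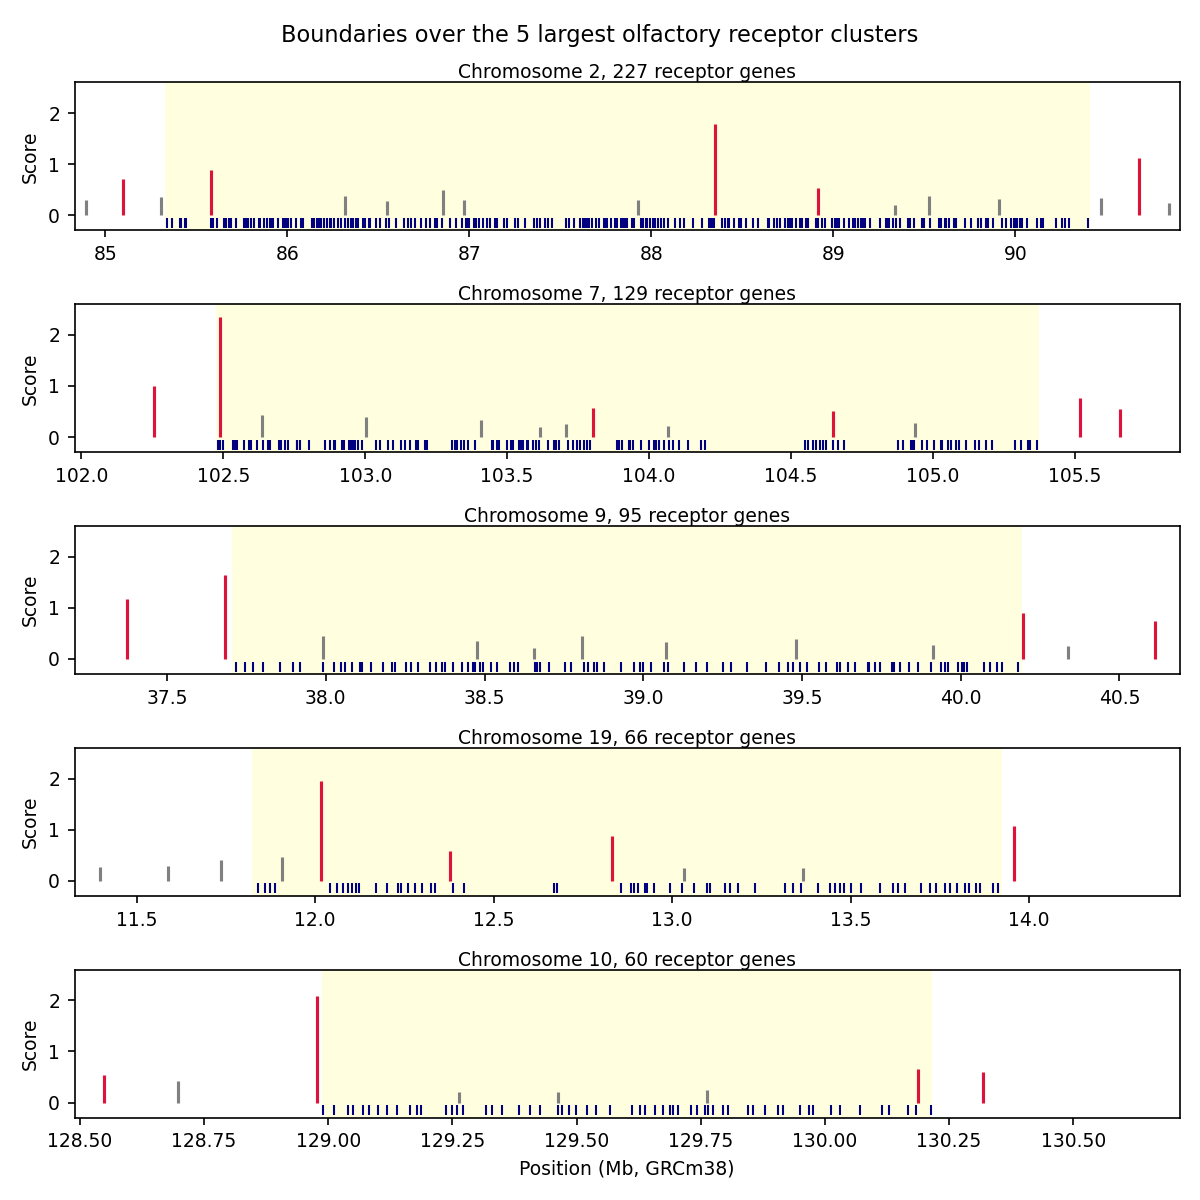
Boundaries over the 5 olfactory receptor clusters with the most genes (shaded), with position in Mb of GRCm38 on the x axis and boundary score on the y axis; red lines are strong and grey lines weak boundaries, and blue ticks are receptor gene starts. The cluster on chromosome 9 holds 7 boundaries and no strong one.

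Boundaries carried matches to the consensus of CTCF, the zinc finger protein that stops cohesin loops. Within 10 kb of the 7841 boundaries lay 2515 matches to CCASYAGRKGGC, 0.321 per boundary against 0.125 by shifts. The ratio was 2.56 ± 0.055 (jackknife standard error over chromosomes, permutation p = 1e-04), and 1.61 for intervals extended by 50 kb. A match was present at 33.7% of strong boundaries (Wilson 95% interval 32.3 to 35.1%) and at 17.4% of weak ones (16.2 to 18.6%). The genome held 12728 matches, and an exact consensus finds only a part of the sites that CTCF can bind.

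The strand of the matches changed across the boundary. Within 50 kb to the left of boundary midpoints 30.7% of 3254 matches were on the forward strand, and within 50 kb to the right 67.2% of 3193. The difference was 36.5 percentage points, against a standard deviation of 0.789 with strands permuted within boundaries (p = 1e-05, the smallest that 100000 permutations can give). Matches on both sides mostly pointed away from the boundary into the adjoining domains.

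Strong boundaries were richer than weak ones in GC, gene starts and CTCF matches. Their windows averaged 44.1% GC against 41.8%, a difference of 2.27 points. They had 0.425 matches per boundary against 0.204, and 41.0% against 26.8% had a protein-coding TSS within 10 kb. The adjusted p was 1e-04 for each of the 3 measures, the smallest that 10000 rotations of the class labels can give. From the lowest to the highest quartile of scores, the share with a gene start was 23.4, 30.9, 39.8 and 43.1%, and the share with a match 13.9, 22.0, 31.2 and 36.8%.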

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

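Mostly unique bins, lists matched on GC content and all strata of composition were chosen only after the results were seen. The ratios for gene starts (1.38 to 3.03) and CTCF matches (1.61 to 3.54), the strand difference (26.9 to 40.4 points) and the contrasts of strong and weak boundaries kept their direction and stayed past the threshold under all alternatives run on them. The lower strong share inside receptor clusters stayed past it with other cluster gaps and in mostly unique bins (−24.1 to −18.7 points). It also did against boundaries of like GC content, gene starts and motif matches (−10.9 points, permutation p = 0.0166) and of like GC content over 1 Mb (−10.5 points, permutation p = 0.0385), but not with gene starts set aside (−7.31 points, permutation p = 0.121). The tests against boundaries of like composition took boundaries as independent. Of the alternatives to the main comparisons, 53 kept the direction and the side of the threshold or, for values with no test, lay within the limits set for them; 14 moved such an untested value or count and 1 brought a result past the threshold. With strong boundaries alone the number was 4137, the strong share 100% by construction and the spacing 405 kb, and with scores at or above the median these were 3921, 100% and 420 kb. Without chromosome X the strong share was 53.9%. The density of chromosome X over the autosome median was 0.863, and 0.524 with strong boundaries alone. It was not computed over mostly unique bins. The density ratio in olfactory receptor clusters was 0.485 with strong boundaries alone and 0.913 to 0.970 otherwise. In place of 6 lists above and 1 below the expectation, there were 3 above and 2 below with strong boundaries alone, and 3 above and 2 below against lists matched on neighbouring gene starts. With GC content matched as well there were 3 above and 1 below, over bare intervals 4 above and 0 below, and over mostly unique bins 6 above and 0 below. The Zfp genes turned to 0.755 and 0.778 against both kinds of matched list, where dense gene neighbourhoods no longer count; the cause of the other shifts was not tested. Single lists otherwise kept their side of the threshold in 116 cases, lost it in 13 and gained it in 5. Merging boundaries within 50 kb changed nothing, since none lay closer than 60 kb. Its values are among the 53 and could not have differed, nor could the exact p of chromosome X pass the threshold. No paired analysis was possible because there is 1 group and its replicates were pooled before calling, and for the same reason neither replicate could be left out. What depth limits is unknown, since contact numbers were not analysed here.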

Other observations

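The tests of other gene classes, gene strand, motif and gene start combinations, boundary-free stretches and chromosome correlations were chosen only after the results were seen. The same holds for repeated sequence at vomeronasal genes and for composition of receptor clusters, with or without gene starts.

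Transfer RNA genes had the highest ratio of the 8 gene classes outside the fixed lists. The classes were not tested against each other, and no lists matched on neighbouring gene starts were drawn for them. For all protein-coding genes the ratio was 2.12 ± 0.072. Of 403 tRNA genes, 75 (18.6%) lay within 10 kb of a boundary, against 7.72% by shifts, a ratio of 2.41 ± 0.60 (adjusted permutation p = 2e-04 over 8 classes). Antisense genes (ratio 1.57), small nuclear RNA genes (1.29, adjusted permutation p = 0.00448), long intergenic RNA genes (1.22) and processed pseudogenes (1.08, adjusted p = 0.0379) were above shifts too. Unprocessed pseudogenes were near boundaries in 83 of 1952 cases, a ratio of 0.557 ± 0.077 (adjusted permutation p = 2e-04). MicroRNA genes (1.24, adjusted permutation p = 0.118) and small nucleolar RNA genes (1.21, adjusted p = 0.134) did not pass the test. Across the 20 chromosomes, boundary density went with protein-coding genes per Mb. Pearson r was 0.690 (permutation p = 5.2e-04, adjusted 0.00104) and Spearman rho 0.656 (permutation p = 0.00234, adjusted 0.00273). The adjustment covered both coefficients of the 2 relations, with genes and with GC content. Without chromosomes 7 and 11, r was 0.654. With GC content r was 0.750 (permutation p = 3.1e-04, adjusted 0.00104) and rho 0.642 (permutation p = 0.00273, adjusted 0.00273), and r fell to 0.495 without chromosomes 11 and X.

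Gene starts faced away from boundaries slightly more often than toward them. Within 50 kb to the left of midpoints 46.1% of 4954 gene starts were on the forward strand and to the right 53.9% of 4769, a difference of 7.81 points (p = 1e-05, the smallest that the permutations can give). Both a CTCF match and a gene start lay within 10 kb of 700 boundaries, 8.93% against 2.99% by shifts, and neither lay near 3818, 48.7% against 74.8%. The longest stretch without a boundary was 11.6 Mb of chromosome X (24240001 to 35835000), a region that holds Slx and Btbd35f genes. Others held Vmn1r genes (chromosome 7, 19970001 to 23525000), Zfp genes (chromosome 2, 174905001 to 178405000), alpha-defensin genes (chromosome 8, 19520001 to 21945000) and Scgb genes (chromosome 7, 31395001 to 33745000). In the 12 longest stretches 11.4 to 39.9% of 50-mers were unique, against a mean of 88.6% over all bins.

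The strong share of chromosome X was −21.7 points from the autosome median. Sequence composition may account for part of this, since autosomal boundaries of the same GC content, gene starts and motif matches predicted 40.4%, yet the observed share was −7.48 points from that prediction, beyond any autosome (−5.42 to 4.00). Sequence that does not map uniquely in the boundary's own bin is argued against as the whole cause, because among 268 boundaries in bins at least 90% unique the gap was still −19.9 points. Repeated sequence farther around the boundaries was not tested. The lower copy number of chromosome X in males and its inactive copy in females remain untested explanations, as the sexes were mixed. A lower number of contacts on chromosome X could also weaken calls there, and contact numbers were not analysed here.

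The weak boundaries inside olfactory receptor clusters were weighed against the same kinds of cause. With class permuted among boundaries of like GC content, gene starts and motif matches the strong share remained −10.9 points from expectation (standard deviation 4.44, p = 0.0166), with GC of the surrounding 1 Mb −10.5 points (4.90, p = 0.0385), and in bins at least 90% unique −23.5 points from outside (n = 51, p = 6e-04). The first of these counts the receptors' own starts, and with gene starts set aside the gap was −7.31 points (standard deviation 4.70, permutation p = 0.121), so that local GC and motif content and a property of the clusters cannot be told apart. Composition therefore may account for much of the difference of −23.8 points. The permutations within strata took boundaries as independent. Uniqueness was measured in the boundary's own bin, so repeated sequence farther around it was not tested. No biological explanation was tested, since there is 1 group.

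The scarcity of vomeronasal receptor starts near boundaries may be a matter of repeated sequence. Of the 326 starts, 87 (26.7%) lay in mostly repeated bins, against 4.83% of all protein-coding genes and 2.03% of olfactory receptor genes, and 0 of these 87 were near a boundary. Of the other 239, 11 were (4.60%), but these genes lie in tandem arrays, such as that in the stretch on chromosome 7 from 19970001, so the starts are not independent. Over mostly unique bins the ratio was 0.703 (adjusted permutation p = 0.301), between the first value of 0.434 and 1, so that the loss of callable sequence and a scarcity of boundaries at these genes cannot be told apart. No biological explanation was tested.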
